A study of Homo sapiens with 2 samples.

How the data were processed

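RNA from BEAS-2B cells kept for 48 h in 0 or 0.5 mM NiCl2 was hybridised to one-colour (Cy3) Agilent human gene expression arrays, 1 array per dose, as the labels give it. Doses come from the sample descriptions. Per the labels' protocols, RNA was prepared with a kit for blood RNA and depleted of globin transcripts, although the sample is a cell line, and how far that text applies to these samples is not known. The labels also call the measurement miRNA expression, which the probes on the arrays do not bear out.

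The deposited scanner files hold intensity values per spot on a linear scale. Per the file headers, they were made with Feature Extraction 10.5.1.1, which subtracted background and detrended each array, and put a small positive stand-in where a spot was not above background; the submitters' processing notes name Agilent Feature Extraction 9.1 instead. The arrays were not scaled to each other. The series value table equals the scanner's processed intensity on both arrays in 100% of spots, so it is linear, uncentred and unscaled, with column medians of 32.8 (untreated) and 25.8 (NiCl2). Per the file headers, the slope of the E1A spike-ins and the net signal of the negative controls were outside Agilent's range on both arrays. Both arrays lay on 1 slide and shared 1 scan, so no batch could be tested.

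Each array had 62976 spots, 4259 of them controls. Control spots and spots marked as outliers (307 and 392) were left out, and no spot was saturated. Spots of a probe were averaged on the log2 scale, and a probe was called well above background where at least 0.5 of its spots were. The 75th percentile of non-control signals was 265 on the untreated and 167 on the NiCl2 array. The log2 processed intensity was scaled by subtracting each array's 75th percentile over the probes well above background on both arrays. The plan was to scale over all probes unless under 50% were detected. That condition was ambiguous here, with 51.6%, 49.1% and 46.0% of probes well above background on the untreated array, the NiCl2 array and both. It was taken as met, and this was settled after a first look at values scaled over all probes, which are given as an alternative. The log2 offset between the arrays was -0.80.

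Genes were named through the accession of each probe in the RefSeq gene table of GRCh38, which matched 28172 probes (55.7%); other probes kept the name in the files. Coordinates are those of the files (hg19). A gene took the value of its brightest probe well above background on both arrays. Of 3486 genes with several such probes, 1232 had probes that disagreed, which means another sign or a log2 difference further than 1 apart. A gene well above background on 1 array only was given a lower bound.

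With 1 array per group no test was run and no p-value is given. Genes were counted at 2-fold, and 33 gene lists were compared with 10000 random lists matched on mean signal in 20 bins. Named genes followed a rule fixed before the data were examined: the 15 highest and 15 lowest log2 differences above the median signal with an established symbol, the 5 largest bounds in each direction, and up to 4 members of each list by size, with 1 from each side where a list had members past 2-fold on both. Other members named in the text, such as VEGFA, EGLN1, BNIP3, PFKM, SLC30A1, MTF1, ATF4, CDH1, EGLN3, PDK1, KDM4C, TFRC, HFE, FBL, NOP58 and the NRF2 and inflammatory genes above background on 1 array only, were chosen after their values were seen. Some genes that the rule names are not reported here. The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, no scaling, other filters on dim probes, the mean over a gene's probes, the series value table, other fold thresholds and random lists without matching. Scaling to the 75th percentile of all probes and to the E1A spike-ins was added after the data had been seen.

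The calculation was tested on simulated data made from the untreated array with the measured spot noise, on the 26132 probes well above background there, each taken as a gene, for the NiCl2 against untreated comparison. All 50 genes raised 4-fold and all 50 lowered 4-fold were recovered at the 2-fold threshold, 3 of 100 genes changed 1.41-fold were called, and so were 0.023% of unchanged genes. Of 100 lists of unchanged genes, 7 fell outside the central 95% of random lists. Changed genes were drawn from detected probes above a set signal. Detection was copied from the untreated array, so no lowered gene could drop out. Noise on the difference had the same SD, 0.28, at every signal, so recovery and false calls largely followed from that setting. They do not speak to dim genes, where the measured SD of the difference was 0.38. Simulated noise was technical only and holds no variation between cultures. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.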

Results

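Gene expression was measured in BEAS-2B cells, an SV40-immortalised line of human bronchial epithelial cells grown in serum-free medium, after 48 h with 0 or 0.5 mM nickel chloride (NiCl2). The question set by the design was which transcripts differ between nickel-exposed and unexposed cells. Each dose was represented by 1 one-colour Agilent array, so the data hold no replicates: no test was possible, and each value below describes a pair of arrays. Each array carried 50597 non-control probes, of which 51.6% were well above background on the untreated array and 49.1% on the NiCl2 array. The number of arrays limits the precision. The only measured error was technical, over 551 probes printed in several spots, with a median of 10 used per probe on the untreated array. For 1 spot each, the log2 difference between the arrays had an SD of 0.28. This SD was 0.38 among the dimmer and 0.10 among the brighter of these probes. Normalized log2 signals correlated across genes at r = 0.95 (Pearson), and genes are not independent replicates. The sample descriptions speak of miRNA expression, whereas the platform and the series design are for gene expression, and the values below are those of gene expression probes.

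Hypoxia-inducible, glycolytic and metallothionein transcripts were much higher on the array of NiCl2-exposed cells than on that of untreated cells. NDRG1, a hypoxia- and stress-induced gene, was 201-fold higher on the NiCl2 array, ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 91.6-fold higher, and HK2, a hexokinase, was 41.7-fold higher. Lists of ATF4 and CHOP targets of the amino acid response and of oxidative phosphorylation subunits lay low, with 14 of 29 and 8 of 27 members at least 2-fold lower, among them PSAT1, an enzyme of serine synthesis, 8.06-fold lower, and NDUFA9, a subunit of respiratory complex I, 3.21-fold lower. Of 18698 genes well above background on both arrays, 2401 were at least 2-fold higher and 1615 at least 2-fold lower on the NiCl2 array, and 442 and 172 passed 4-fold.

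The balance of higher and lower genes depended on how the arrays were scaled and on which genes were counted. With the scaling used here, 59.8% of the genes past 2-fold were higher and the median log2 difference of all genes was 0.30, so medians of gene lists are given below relative to that value. The share of higher genes among those past 2-fold was 44.985% with quantile normalization, 40.6% with scaling to the median, 37.7% with scaling to the 75th percentile of all probes, 10.2% without scaling and 9.24% with scaling to the E1A spike-in RNAs. It was 47.3% among the brighter genes by mean signal, with 1069 higher and 1192 lower. Without scaling each log2 difference was lower by 0.80, and with E1A scaling by 0.85, a move of over 1.5-fold for each of the 152 genes named here that were well above background on both arrays. Of the 137 of them past 2-fold, 31 and 33, each among the higher genes, were then no longer past it. Among 11643 genes with a protein-coding RefSeq accession, 1276 were higher and 1415 lower by 2-fold, whereas among the 7055 other genes 1125 were higher and 200 lower.

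Of the 15 highest genes, 6 were on the list of hypoxia-inducible genes fixed beforehand (NDRG1, ANGPTL4, HK2, PFKFB4, HILPDA and PFKFB3) and ALDOC was on that of glycolysis. DEPP1 (C10orf10 in the files), a FOXO-regulated gene, stood 245-fold higher on the NiCl2 array, with a signal of 72.0 on the untreated and 10140 on the NiCl2 array and a scanner error of 0.23 on the log2 difference. Its probe (NM_007021) lies on chromosome 10 at 45471710 to 45471769 of hg19, minus strand. The NDRG1 probe (NM_006096) lies on chromosome 8 at 134249719 to 134249778, minus strand, and read 1132 and 130520. ANGPTL4 (NM_139314) was probed on chromosome 19 at 8439197 to 8439256, plus strand, and HK2 (NM_000189) on chromosome 2 at 75120331 to 75120390, plus strand. Exon and untranslated-region annotation of these positions was not used here. COXFA4L2 (NDUFA4L2 in the files), TMEM158, PFKFB4, the minor spliceosomal RNA RNU6ATAC, ALDOC, RIMKLA, HILPDA, PFKFB3, PI3 and CD86 were between 24.6-fold and 32.8-fold higher. HMBOX1 was also among the 15 highest at 24.6-fold, but its probes disagreed, with log2 differences of 4.62, 0.51 and -0.09.

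**Figure D1:**
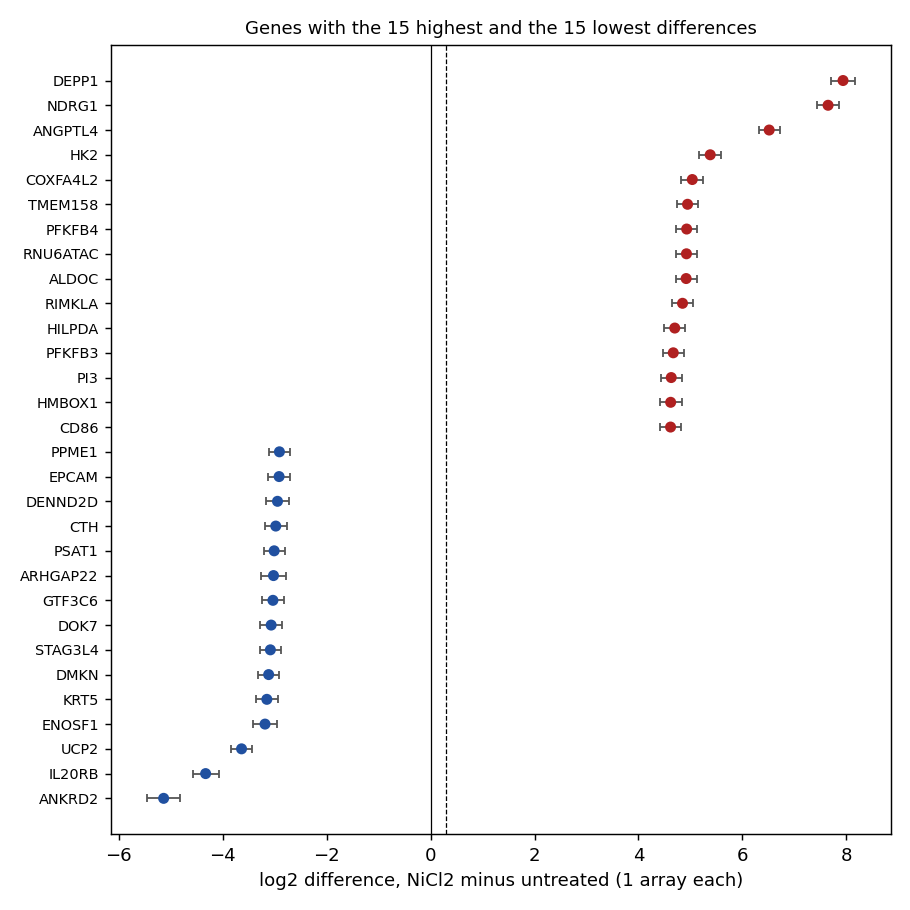
Log2 difference (NiCl2 minus untreated) of the 15 highest and the 15 lowest genes above the median signal, 1 array per dose. Points are genes, bars are the scanner's error model for the difference, the solid line marks 0 and the dashed line the median of all genes (0.30); DEPP1 stands highest at 7.94 and ANKRD2 lowest at -5.14.

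At the other end, ANKRD2, a stretch-responsive ankyrin repeat protein, was 35.2-fold lower on the NiCl2 array, with signals of 1976 and 32.2. IL20RB, a subunit of the interleukin 20 receptor, was 20.1-fold lower and UCP2, a mitochondrial carrier, 12.4-fold lower. ENOSF1, KRT5, DMKN, STAG3L4, GTF3C6, ARHGAP22, PSAT1, CTH, DENND2D, EPCAM and PPME1 were between 7.51-fold and 9.101-fold lower. DOK7 was 8.39-fold lower by its brighter probe, whereas its other probe had a log2 difference of 0.31. With normexp background correction 18 of the 152 named genes moved by over 1.5-fold and 0 of those past 2-fold changed sign. DEPP1 had a log2 difference of 6.95 and ANKRD2 one of -3.59. GRHL2, FOS, FOSB and RAB25, named below, were also among the 18, at 1.97, 2.275, 1.55 and -1.75. Of the 137, 13 were no longer past 2-fold with normexp, 12 with quantile normalization and 11 with the mean over probes. DNAJC3, DNAJB9, DNAJA1, ASPM, KDM6B, MIR17HG and ZC3H12A were among them for both normexp and quantile normalization.

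Some genes were well above background on 1 array only, and for these the fold is a lower bound, computed against the lowest signal among probes well above background or the dim probe's own signal, whichever was higher. Of 1088 such genes on the NiCl2 array, 975 had a bound of at least 2-fold, and of 1986 on the untreated array, 289 did. Carbonic anhydrase CA9, a HIF target, was at least 743-fold higher on the NiCl2 array. NOG, an antagonist of bone morphogenetic proteins, was at least 54.2-fold higher, TNFAIP3, an NF-kB inhibitor, at least 45.2-fold, ZP1 at least 38.7-fold and KRT34 at least 30.0-fold. In the other direction GPX8, CEP41, KLHDC9 and TAF1B were at least 9.22-fold, 8.85-fold, 8.55-fold and 7.39-fold lower. These bounds depend on the background correction: with normexp they were at least 186-fold for CA9, 14.4-fold for NOG, 13.0-fold for TNFAIP3, 10.483-fold for ZP1 and 9.47-fold for KRT34 higher, and 2.79-fold, 2.92-fold, 2.34-fold and 2.01-fold lower for GPX8, CEP41, KLHDC9 and TAF1B. With the mean over its probes the GPX8 bound was 3.64-fold.

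Gene lists fixed before the data were examined were then compared, 33 in all. For each list the median of its members is given relative to all genes, with its percentile among 10000 random lists of the same size matched on signal, as a description of these arrays. Because brighter genes had lower differences on the whole, a list can lie below the median of all genes and yet high among matched lists. Random lists were drawn from genes with and without a protein-coding accession, whose median log2 differences were 0.08 and 0.52. A list of protein-coding genes can therefore lie low in part for that reason. Random lists of protein-coding genes alone were not drawn.

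Hypoxia-inducible genes listed apart from glycolysis were higher as a group. The division is not strict, since the hexokinase HK2 is on this list and HK1 on that of glycolysis. Of 38 measured, 35 were at least 2-fold higher and 0 were lower by 2-fold, the median was 2.19 above all genes, and the percentile was 100. Besides NDRG1, ANGPTL4 and HK2, PFKFB4, which sets the level of fructose 2,6-bisphosphate, was 30.4-fold higher. VEGFA, the vascular growth factor, had a log2 difference of 2.38, the prolyl hydroxylase EGLN1 3.83 and the mitophagy receptor BNIP3 3.82. A further 3 members were well above background on the NiCl2 array only, CA9, EGLN3 and PDK1. PDK1 was at least 8.24-fold higher, and its bound with normexp is not given here. KDM4C was well above background on the untreated array only, with a bound of 0.989-fold, which does not show it lower. Glycolytic genes were higher as a group, with 17 of 20 past 2-fold, a median of 2.06 above all genes and a percentile of 100. ALDOC was 30.2-fold, ENO1 12.1-fold, ENO2 11.2-fold and ALDOA 10.2-fold higher, and PFKM, at a log2 difference of -0.13, was the only measured member below 0.

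Metallothioneins and zinc transporters had 12 of 17 members at least 2-fold higher and 0 lower, a median of 2.78 above all genes and a percentile of 100. MT1G was 31.1-fold higher, MT1X 23.3-fold, MT1H 14.5-fold and MT1E 13.4-fold. With normexp MT1G, at a signal of 39.3 on the untreated array, had a log2 difference of 3.52. Metallothionein 1 genes are near-identical copies, so the share of each is uncertain. SLC30A1, a zinc exporter with a sequence of its own, had a log2 difference of 1.84, and the metal-responsive transcription factor MTF1 -0.05. Iron uptake and storage genes did not stand apart, with 0 of 9 past 2-fold in either direction and a percentile of 80.5. CYBRD1, ACO1, SLC11A2 and STEAP3 had log2 differences of -0.94, -0.89, 0.89 and 0.87, and the CYBRD1 probes disagreed. The transferrin receptor TFRC was well above background on the NiCl2 array only, at least 13.0-fold higher. HFE was so on the untreated array only, at least 1.94-fold lower. Bounds of both with normexp, which lowered each bound checked, are not given here.

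Lists of stress responses took different positions. NRF2 antioxidant targets were split, with 6 of 24 at least 2-fold higher, 3 lower and a percentile of 77.4. HMOX1, heme oxygenase 1, was 7.33-fold higher, the pentose phosphate enzyme TKT 5.40-fold and OSGIN1 3.14-fold, while SLC48A1 was 2.47-fold lower by one of a pair of disagreeing probes. A further 4 members, NQO1, GCLC, SLC7A11 and ME1, were well above background on the untreated array only, with bounds from 1.08-fold to 1.92-fold lower. Targets of ATF4 and CHOP in the amino acid response were lower, with 14 of 29 past 2-fold, 1 higher, a median of -1.25 relative to all genes and a percentile of 0.0. PSAT1 was 8.06-fold, the cysteine-synthesis enzyme CTH 7.89-fold and NUPR1 7.27-fold lower, and ATF4 itself had a log2 difference of 0.09. ATF3 was 2.03-fold higher, but its log2 difference was 0.92 with normexp, 0.975 with the mean over probes and 0.17 with E1A scaling. Endoplasmic reticulum chaperones had 5 of 18 past 2-fold higher, 0 lower and a percentile of 85.5, led by CANX at 3.64-fold, with DNAJC3, HSP90B1 and DNAJB9 between 2.07-fold and 2.15-fold. Heat shock genes had 4 of 17 higher, 0 lower, a median of 0.33 above all genes and a percentile of 98.98, or 95.92 without matching. HSPA1A and HSPA1B, whose near-identical sequences leave their values uncertain, were 4.36-fold and 3.49-fold higher, and DNAJA1 was 2.003-fold higher. HSP90AA1 was 3.70-fold higher by its brighter probe, and its other probe had a larger log2 difference of 3.92. The heat shock median was -0.17 without scaling and -0.22 against the E1A spike-ins. Autophagy and lysosome genes had 0 of 23 higher and 2 lower, with a percentile of 4.05, or 0.48 without matching. ATP6V1H was 3.08-fold lower, or at a log2 difference of -0.945 with normexp, LAMP1 and CTSD had log2 differences of -0.95 and 0.95, and ATG7 was 2.32-fold lower with a disagreeing second probe.

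**Figure D2:**
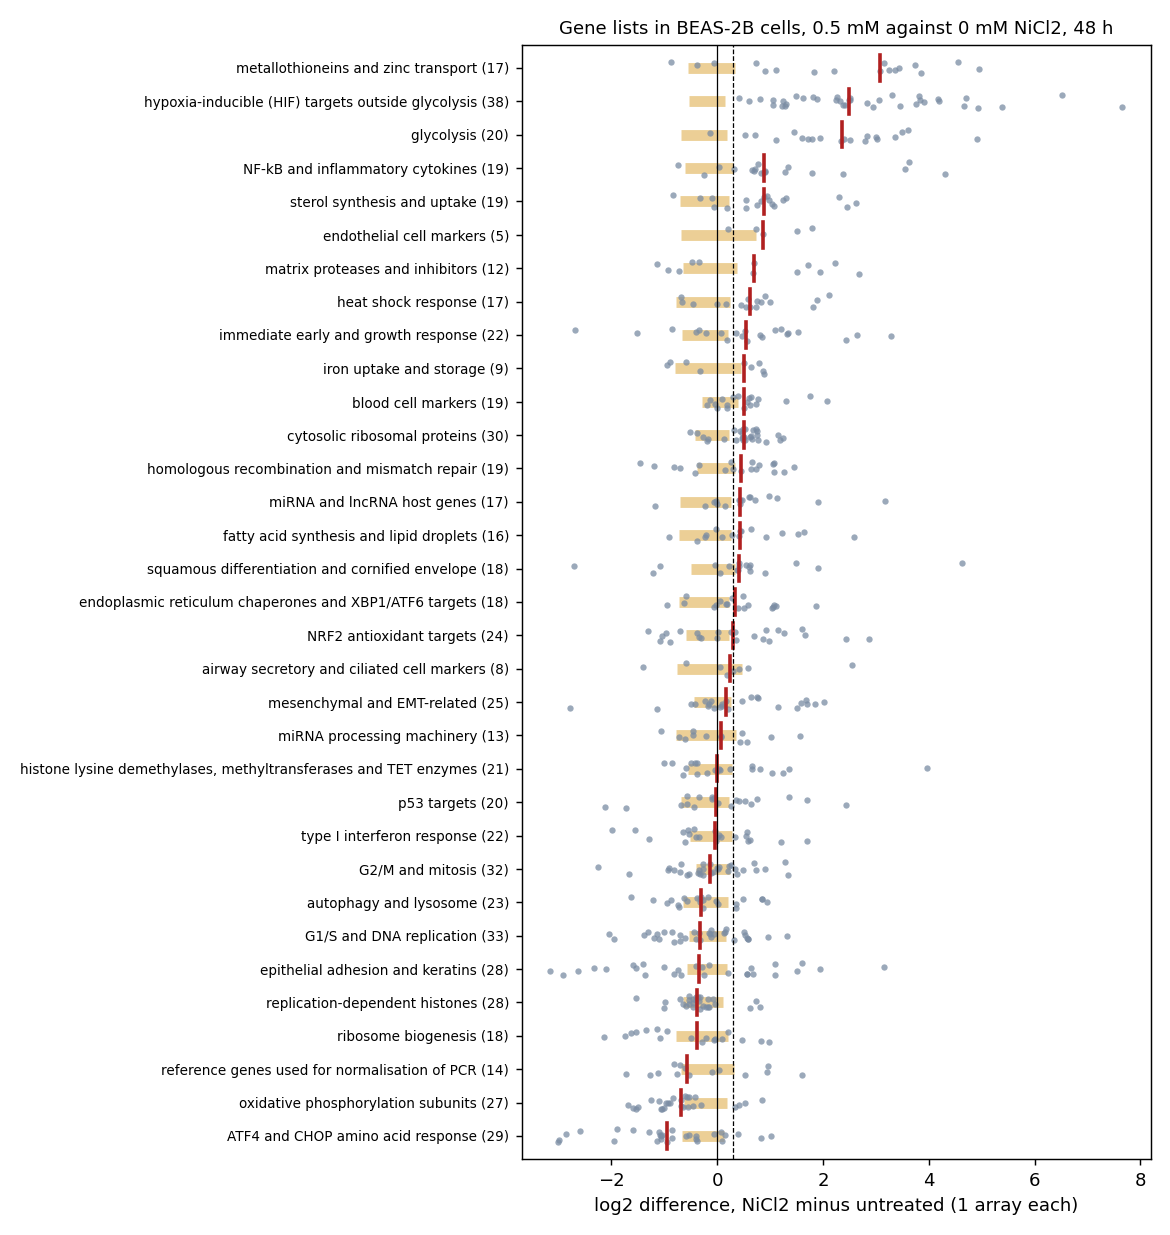
Log2 difference (NiCl2 minus untreated) of the measured members of each of 33 gene lists, 1 array per dose, with the number of members in parentheses. Points are genes and red ticks are list medians. Yellow bars span the central 95% of medians of signal-matched random lists. The bars are drawn relative to the median of all genes, so they sit 0.30 too low against the points and ticks. Percentiles in the text are free of this shift. The solid line marks 0 and the dashed line the median of all genes (0.30). Metallothioneins, hypoxia-inducible genes and glycolysis lie far above their bars, and the ATF4 and oxidative phosphorylation lists lie below theirs, with or without the shift. Without scaling, and with E1A spike-in scaling, 15 of the medians above 0 lie below 0.

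NF-kB and inflammatory genes were higher as a group, with 7 of 19 past 2-fold, 0 lower, a median of 0.59 above all genes and a percentile of 99.98. The unadjusted list median of 0.89 was close to the 0.85 of the E1A spike-ins, so the list was hardly higher against these. IL32 was 19.8-fold higher by its brighter probe, with disagreement on size between its probes. RELB, an NF-kB subunit, was 12.3-fold, the cytokine IL11 11.6-fold and the superoxide dismutase SOD2 5.21-fold higher. A further 6 members, TNFAIP3, CCL5, CCL20, CSF2, BIRC3 and TLR2, were well above background on the NiCl2 array only. On the untreated array only were 2 members, CXCL5 and IL36G, with bounds of 1.36-fold and 0.84-fold. A bound under 1 does not show a lower value on the NiCl2 array. Type I interferon response genes did not stand apart, with 2 of 22 higher, 3 lower and a percentile of 9.61. ISG20 was 3.25-fold higher, and USP18, STAT2 and MX1 were 3.98-fold, 2.95-fold and 2.43-fold lower, with USP18 at a log2 difference of -0.93 with normexp. Immediate early genes had 8 of 22 higher, 2 lower, a median of 0.24 above all genes and a percentile of 98.4, or 93.1 without matching. FOS, FOSL1 and FOSB, which encode AP-1 subunits, were 9.78-fold, 6.28-fold and 5.43-fold higher, and the growth factor AREG was 6.40-fold lower. This list's median was -0.26 without scaling and -0.31 against the E1A spike-ins.

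Among proliferation and DNA damage genes, those of the G1/S transition and DNA replication lay low, with 1 of 33 higher, 8 lower, a median of -0.63 relative to all genes and a percentile of 0.86. GINS2 and CDC45, parts of the replicative helicase, were 4.10-fold and 3.87-fold lower, RFC4 was 2.61-fold lower and the licensing factor CDT1 2.51-fold higher. Mitotic genes had 2 of 32 higher, 2 lower, a median of -0.43 relative to all genes and a percentile of 1.85. The unadjusted medians of the replication and mitotic lists were -0.325 and -0.13, against 0.08 for genes with a protein-coding accession. CCNB2 was 4.75-fold lower, and CENPF and ASPM were 2.52-fold and 2.44-fold higher. CCNB1 was 3.16-fold lower by its brighter probe, and its other probe had a log2 difference of 0.07. Replication-dependent histones, which share sequence, had 0 of 28 higher, 2 lower and a percentile of 1.45. H1-3 was 2.91-fold and H1-1 2.004-fold lower, and H2AC4 and H3C15 had log2 differences of -0.99 and 0.82. Targets of p53 did not stand apart, with 3 of 20 higher, 2 lower and a percentile of 27.5: SERTAD1 was 5.44-fold and BBC3 3.24-fold higher, and GDF15 and TP53I3 were 4.33-fold and 3.29-fold lower. Homologous recombination and mismatch repair genes had 5 of 19 higher, 2 lower and a percentile of 76.4. MGMT was 2.29-fold lower, and FANCA and XRCC3 were 2.74-fold and 2.41-fold higher by their brighter probes, with others in disagreement.

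Epithelial adhesion and keratin genes were split, with 6 of 28 higher, 10 lower, a median of -0.65 relative to all genes and a percentile of 1.24. The basal keratin KRT5 was 8.88-fold lower, the adhesion molecule EPCAM 7.54-fold and RAB25 6.20-fold lower, and the transcription factor GRHL2 was 8.90-fold higher. E-cadherin, CDH1, had a log2 difference of -2.10. Mesenchymal genes did not stand apart as a list, with 7 of 25 higher, 2 lower and a percentile of 31.0. SNAI1 was 4.08-fold, COL6A1 3.61-fold and LGALS1 3.24-fold higher, and TAGLN was 6.85-fold lower. Matrix proteases and their inhibitors had 5 of 12 higher, 1 lower, a median of 0.39 above all genes and a percentile of 97.6, or 96.98 without matching. PLAUR, TIMP1 and ADAMTS1 were 6.40-fold, 4.68-fold and 3.85-fold higher. PLAU was 2.19-fold lower, or at a log2 difference of -0.73 with the mean over its probes. The list's median was -0.11 without scaling and -0.15 against the E1A spike-ins. Squamous differentiation genes had 3 of 18 higher, 3 lower and a percentile of 77.2. Among them the protease inhibitors PI3 and SLPI were 24.8-fold and 3.75-fold higher, TGM2 was 2.82-fold higher and CSTA 6.51-fold lower.

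Markers of other cell types gave no list that stood apart. Airway secretory and ciliated markers had 1 of 8 higher, 1 lower and a percentile of 45.03. MUC1 was 5.82-fold higher, with probes that disagreed on size only. TFF3 was 2.65-fold lower and MUC4 had a log2 difference of -0.59, each with probes that disagreed in sign. SCGB3A1 had a difference of 0.59. Blood cell markers had 3 of 19 higher, 0 lower and a percentile of 75.1. HBA2, a globin with a near-identical copy and probes that disagreed on size only, was 4.20-fold higher. Its signal was 58.2 on the untreated and 140 on the NiCl2 array. CD68 was 3.38-fold and CSF1R 2.45-fold higher, and CD14 had a log2 difference of 0.77. Endothelial markers had 2 of 5 higher, 0 lower and a percentile of 93.9, with EGFL7 3.49-fold and VWF 2.85-fold higher and ROBO4 and ESAM at log2 differences of 0.86 and 0.73.

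Lists of lipid and energy genes took different positions. Sterol synthesis and uptake genes had 7 of 19 higher, 0 lower, a median of 0.58 above all genes and a percentile of 100. The unadjusted list median of 0.88 was close to the 0.85 of the E1A spike-ins. INSIG1, a sterol-regulated inhibitor of SREBP processing, was 6.19-fold higher, MVD 4.95-fold and DHCR7 2.47-fold. Fatty acid synthesis and lipid droplet genes had 4 of 16 higher, 0 lower and a percentile of 90.3. PLIN2, a lipid droplet coat protein, was 6.02-fold higher by one of a pair of probes that disagreed on size, and FADS2, SCD and FASN were 3.14-fold, 2.87-fold and 2.33-fold higher. Oxidative phosphorylation subunits had 0 of 27 higher, 8 lower, a median of -0.99 relative to all genes and a percentile of 0.03. After NDUFA9, ATP5F1A and SDHC were 3.01-fold and 2.87-fold lower.

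Translation and RNA-related lists came last. Cytosolic ribosomal proteins, whose pseudogenes share their sequence, had 3 of 30 higher, 0 lower and a percentile of 95.9: RPL10, RPL23 and RPL7 were 2.36-fold, 2.27-fold and 2.22-fold higher and RPLP1 had a log2 difference of 0.92. With quantile normalization RPL10, RPL23 and RPLP1 had log2 differences of 0.57, 0.74 and 0.25. Ribosome biogenesis genes had 0 of 18 higher, 7 lower and a percentile of 4.93, or 0.41 without matching. POLR1A, the largest subunit of RNA polymerase I, was 4.38-fold lower, and GAR1, DKC1 and NOP56, proteins of small nucleolar ribonucleoproteins, were 3.36-fold, 3.09-fold and 2.90-fold lower. Histone lysine demethylases, methyltransferases and TET enzymes had 4 of 21 higher, 1 lower and a percentile of 14.4. TET1, a 5-methylcytosine dioxygenase, was 15.7-fold higher, KDM2B and KDM6B were 2.58-fold and 2.36-fold higher, and EHMT1 was 2.02-fold lower with disagreeing probes. The miRNA processing machinery had 2 of 13 higher, 1 lower and a percentile of 37.5, with TNRC6B 2.94-fold and ZC3H12A 2.02-fold higher, DROSHA 2.09-fold lower and AGO1 at a log2 difference of -0.72. Host genes of miRNAs and other long non-coding RNAs had 3 of 17 higher, 1 lower and a percentile of 90.5. MALAT1 had a log2 difference of 3.17 by its brightest probe, with others in disagreement, UCA1 and MIR17HG were 3.75-fold and 2.18-fold higher, and MIR31HG was 2.25-fold lower.

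Genes often used as PCR references lay low among matched lists. They had 1 of 14 higher, 3 lower, a median of -0.87 relative to all genes and a percentile of 0.49. GAPDH was 3.03-fold higher, with a log2 difference of 0.99 under quantile normalization, 0.80 without scaling and 0.75 with E1A scaling. TBP was 2.42-fold lower, with -0.82 under normexp, and YWHAZ was 3.30-fold lower by the brighter of its disagreeing probes.

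RNA classes were compared after a first look at the data. Small nuclear and nucleolar RNAs stood higher on the NiCl2 array. Nucleolar box C/D and H/ACA RNAs guide the modification of ribosomal RNA, and of the 14 RNAs typed as small nuclear 8 were SNAR RNAs. Of 223 on both arrays, 178 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 difference of 1.43, against 0.07 for 11412 protein-coding genes and 0.47 for 587 long non-coding RNAs. Box C/D RNAs had a median of 1.58 and box H/ACA RNAs one of 1.19. The E1A spike-ins, synthetic RNAs from Agilent, lay at 0.85 on the same scale, and 183 of the 223 small RNAs were above them. Relative to the spike-ins 36 of the 223 were at least 2-fold higher and 5 at least 2-fold lower. Of 20 Cajal body RNAs (SCARNA), typed apart from these, 13 were at least 2-fold higher and 1, SCARNA9, was lower, at a log2 difference of -2.14. Protein-coding genes had a median of -0.78 relative to the spike-ins.

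**Figure D3:**
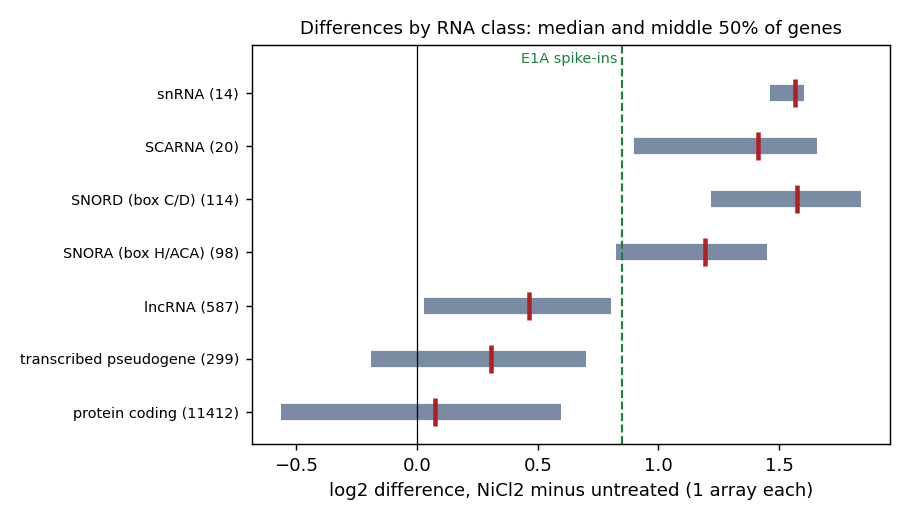
Log2 difference (NiCl2 minus untreated) by RNA class, 1 array per dose, with the number of genes in parentheses. Red ticks are medians, grey bars span the middle 50% of genes, the solid line marks 0 and the dashed line the E1A spike-ins (0.85); the small RNA classes have medians above the spike-ins and the protein-coding, pseudogene and long non-coding classes below them.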

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

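One control probe stood apart between the arrays. The probe for the synthetic transcript ERCC-00113 had a median processed signal of 122.004 on the NiCl2 array and 11.7 on the untreated array, and each of its spots on the NiCl2 array was above each of its spots on the untreated array. It lies outside the gene measurements and entered no comparison.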

How the results depend on the processing

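Alternatives that scale to the 75th percentile of all probes or to the E1A spike-ins were chosen after the data were seen; the others were planned. The counts moved with the scaling, the fold threshold and the filter on dim probes. At least 2-fold higher and lower genes numbered 2401 and 1615 here, 596 and 5253 without scaling, 563 and 5530 with E1A spike-in scaling, and 1497 and 2472 with the 75th percentile of all probes. Higher genes numbered 1600 with scaling to the median and 1637 with quantile normalization, and lower genes 2341 and 2002. Without a filter on dim probes there were 6137 and 2622, with positive and significant signal as the filter 4575 higher, and among the brighter genes by mean signal 1069 higher and 1192 lower, so that the balance turned without a change of scaling. A 1.5-fold threshold gave 6119 and 3214, and a 4-fold threshold 442 and 172. Genes on 1 array only with a bound of 2-fold numbered 975 higher and 289 lower here, 425 and 13 with normexp, 511 and 523 with quantile normalization, 333 and 805 without scaling, 307 and 858 with E1A scaling, and 1523 higher with positive and significant signal. At 1.5-fold 491 were lower, and at 4-fold 261 were higher and 52 lower. For normexp, quantile normalization and the dim-probe filters the cause was not tested.

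Of the 137 named genes past 2-fold, 0 took the other sign with normexp, quantile normalization or the mean over probes. Scalings by a constant could not change a sign, since each moved all genes by less than the 2-fold threshold. The filters on dim probes and the series value table moved 0 of these genes by the technical SD of 0.28. Past 2-fold there stayed 124 with normexp, 125 with quantile normalization, 106 without scaling and 104 with E1A scaling. Medians of 15 of the 33 lists took the other sign without scaling, 15 with E1A scaling, 4 with quantile normalization, 3 with the 75th percentile of all probes and 2 with scaling to the median, and each of these was above 0 in the scaling used here. Those outside the central 95% of random lists were heat shock (-0.171 without scaling, -0.22 with E1A scaling), matrix proteases (-0.105 and -0.154) and immediate early genes (-0.255 and -0.305), by the shift of all genes alone. Under the other 3 scalings the lists were among mesenchymal genes, airway markers, ribosomal proteins and miRNA processing. Without a filter on dim probes the mitotic median was 0.006, and the immediate early median was -0.023 relative to all genes. A further 16 of the 33 medians relative to all genes moved there by at least the technical SD of 0.28. The cause was not tested. Without matching of the random lists, heat shock (95.92), matrix proteases (96.98) and immediate early genes (93.12) came inside the central 95%, and ribosome biogenesis (0.41) and autophagy (0.48) outside it. Named bounds moved for 10 of 10 genes with normexp, where each was smaller, and for 5 with quantile normalization, 10 without scaling, 10 with E1A scaling, 1 with the mean over probes and 1 with positive and significant signal, which gave no value for the others. No saturated spots existed, so leaving them out moved nothing, and the series value table gave identical values, so neither speaks to stability. The slide as a block was not run, since both arrays shared a slide. Without the dim filter no gene is on 1 array only, and neither of those counts was computed among brighter genes. Dim genes are limited most. The SD of the log2 difference between the arrays, for 1 spot each, was 0.38 among dimmer repeated probes against 0.10 among brighter ones. No paired analysis was possible because each dose has 1 array.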

Other observations

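The comparisons of RNA classes and spike-ins below were chosen after their values had been seen, and those of neighbouring genes before.

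Small nuclear and nucleolar RNAs stood above protein-coding genes on the NiCl2 array, with 178 of 223 at least 2-fold higher on the scale used here and 36 relative to the E1A spike-ins, where 5 were at least 2-fold lower. The mRNAs of proteins that bind these RNAs, GAR1, DKC1 and NOP56, were 3.36-fold, 3.09-fold and 2.90-fold lower, whereas those of FBL and NOP58, which also bind them, had log2 differences of 0.83 and 0.47. The median of the class over protein-coding genes of the same signal was 1.389, which argues against a trend of the difference with signal. Against the E1A spike-ins, with equal addition to both arrays assumed, the class lay 0.581 higher. This argues against a loss of mRNA signal alone only if small RNAs and spike-ins were labelled alike, which was not tested. Better recovery of short RNAs could not be ruled out: 21 RNAs of 200 to 400 nt without a poly(A) tail, SCARNA9 among them at -2.14, still had a median excess of 1.419, and the 10 of them within the class one of 1.36, against a length cut-off, but shorter RNAs had larger differences (Spearman rho with length -0.268 over 223 RNAs, which are not independent). A response of the cells to nickel also stays open, since each dose had 1 array.

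Protein-coding genes lay below the E1A spike-ins on the NiCl2 array, with a median of -0.777 for 11412 genes and 85.2% of them below. The 9 E1A probes differed by 0.05 between the unscaled arrays (range 0.008 to 0.121). This argues against weaker labelling or hybridisation of the whole array if equal amounts were added (the labels do not record this). Small RNAs exceeded the spike-ins by 0.581. That argues against less RNA of every kind only if small RNAs and spike-ins were labelled alike, which was not tested. The slope of the spike-ins was outside Agilent's range on both arrays. A lower content of mRNA in the treated cells may be part of the low protein-coding values. With 1 array per dose, it cannot be separated from a loss of mRNA during preparation. If it held, many genes given here as higher would be so only relative to other mRNAs.

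A hypothesis written before its test was that non-coding transcripts at least 4-fold higher lie near protein-coding genes at least 4-fold higher. The set tested was transcripts without a protein-coding accession, and the wording was changed to that after the result. The test was negative. Of 82 such transcripts with a measured protein-coding gene within 50 kb, 8 (9.756%) had one past 4-fold, against a median of 6.10% and an upper limit of the central 95% of 10.976% over 10000 signal-matched draws, so chance was not excluded. Of those 8 pairs, 6 (75%, exact 95% interval 34.9% to 96.8%) lay on the same strand, which met the bound set beforehand for read-through of the neighbour but is too few to decide it, and 4 of the pairs were in the metallothionein cluster, where copies share sequence. AMPD3, picked after its value was seen, was read here by a probe without a protein-coding accession. It had a log2 difference of 2.14 and lay 1356 bp from ADM on the same strand.

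MALAT1, a nuclear long non-coding RNA, was read by 6 probes that separated into log2 differences of 3.17, 3.48 and 3.57 and of 0.20, -0.11 and -0.19.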
